A study of Mus musculus with 8 samples.

How the data were processed

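Gene expression was measured in liver from 8 mice on Affymetrix Mouse Gene 2.0 ST arrays, which read transcripts with probes spread along each gene. All 8 samples are labelled as C57BL/6 mice, female, 6 weeks old, that drank 3% dextran sulfate sodium (DSS), a compound that injures the colon lining and causes colitis, for 7 days. The labels put 4 arrays in a wild-type group and 4 in a group with a mutated interleukin-10 gene (Il10), and the design text counts 4 mice per genotype. The labels tie no array to a numbered animal beyond that, so p-values measure the spread between these samples. Groups and replicate numbers were taken from the sample titles. No untreated mice are part of this comparison, so it is between genotypes under DSS.

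The deposited values are on a log2 scale and come from robust multi-array averaging (RMA), run by the authors in R 3.0.1 per the submitters' processing notes. Background settings, the probe summary used, the treatment of control rows and the genome build are not given in the sources used here. The value table holds 41345 rows for 8 arrays, with values between 2.49 and 13.8, and array medians between 6.09 and 6.22. The number of arrays limits the precision of every value below, and probe-level intensities were not used here.

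Rows were named through the platform annotation. Of the rows, 23521 name 1 gene, 1814 name several, and 16010 are not listed in that annotation and stay unnamed. Of the rows naming 1 gene, 23328 have their gene number and the same symbol in the RefSeq table of assembly GRCm38.p6, which was used for names and for which genes neighbour each other. Windows around Il10 and other genes were taken from distances between genes in that assembly, and no coordinates are given since the build of the array annotation is not named. Rows naming 1 gene gave 22180 genes. For the 1082 genes with more than 1 row, the row with the highest mean over all arrays was kept. Saa1 and Alas2 occur only in rows naming several genes and are not reported alone.

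Genes were compared with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, as arrays labelled knockout minus wild-type arrays, with Benjamini-Hochberg adjustment over the 22180 genes. A gene was called when its adjusted p was below 0.05. All 8 arrays entered the fit without covariates, and no filter on low values was used. Every adjusted p of a gene below is from limma. The value of Il10 was also compared with an exact two-sided permutation test over the 70 arrangements of the 8 arrays.

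For groups of genes, 31 lists of pathway genes and cell type markers with 705 memberships were used, and 632 memberships were measured. Lists were tested with camera in limma at its preset correlation between genes of 0.01, adjusted over the 31 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move 1 way on balance, were alternatives. Counts of list members past the threshold are given over all genes and adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

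The lists, the rule for named genes and the alternatives named first below were fixed before the data were examined. The rule takes Il10, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, up to 4 members of each list with the smallest p, and 11 genes given whatever their values. Those are Hamp, Hamp2, Saa1, Saa2, Lcn2, Id1, Smad7, Bmp6, Tfrc, Cyp7a1 and Alas2. Predicted genes and small RNAs were skipped among the largest changes; 22 higher and 35 lower ones were called with groups apart. The rule named 142 genes.

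The steps were tested on simulated data. With 200 of 22180 genes changed between 4 and 4 arrays, the fit recovered 69.5% at 1.5-fold with 9 false calls, 98.5% at 2-fold with 8 and 98.5% at 3-fold with 7. With 2 lists shifted by 0.5 log2 units, camera called 2 lists and no other. The genes were simulated without correlation between them. The simulation therefore cannot show how often camera calls a list falsely when its genes are correlated.

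The alternatives were a filter leaving out the lowest 40% of genes, every row of the table (control rows cannot be told from unnamed ones), the mean of a gene's rows, a common median per array, quantile normalization, cyclic loess, eBayes with trend and robust settings, array weights, an unmoderated test, the replicate number as a block, each array left out in turn, an adjusted p below 0.1, a 1.5-fold minimum, and windows of 10 and 5 Mb in place of 20 Mb around Il10. Alternatives added after seeing the data were a block for Xist and Y-linked signal, the 4 arrays of each such set alone, and lists without members near Il10. Replicate numbers are shared by both groups but the labels tie them to no litter, batch or day, so the main comparison is unpaired. The closest pair of arrays differed by a root mean square of 0.22 log2 units, so no array repeats another, and correlations between arrays were between 0.976 and 0.994.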

Results

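Liver RNA of 8 mice with DSS colitis was profiled on 8 arrays, 4 from wild-type mice and 4 labelled as IL-10 knockout. Interleukin-10 is a cytokine that restrains inflammation. The comparison asks how the liver transcript profile differs between these genotypes when both have colitis. The values are log2 RMA levels, and errors are SD over n = 4 arrays per group unless SE is stated.

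Il10, the targeted gene (row 17216990), was higher in the arrays labelled knockout. It read 4.95, 5.08, 4.90 and 4.95 in wild-type replicates 1 to 4 and 5.79, 5.69, 6.00 and 6.41 in knockout-labelled replicates 1 to 4. The means were 4.97 ± 0.08 and 5.97 ± 0.32 (SD, n = 4 each), a log2 difference of 1.00 (SE 0.14; limma adjusted p = 0.00851; exact two-sided permutation p = 0.0286, the smallest that 70 arrangements allow). The difference was 1.28 in the 4 arrays with Xist signal described below and 0.72 in the 4 with Y-linked signal, where the adjusted p was 0.0913, and over 19 alternatives the adjusted p lay between 0.00307 and 0.0975. Where the mutation lies relative to the probes of this row is not given in the sources used here, so the row does not check the labels. The means lay at percentiles 19.6 and 36.7 of all genes, and no detection call comes with the values. The row was not lower in the arrays labelled knockout, and every direction below rests on the labels alone.

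The 12 largest rises in the arrays labelled knockout were led by Saa3, Ctse and Chil1. Saa3, an acute-phase serum amyloid, rose from 9.37 ± 0.50 to 12.75 ± 0.42 (SD, n = 4 each; 10.4-fold; limma adjusted p = 0.00267). Ctse, a protease, rose 8.24-fold and Chil1, a chitinase-like protein, 7.92-fold; both genes lie within 20 Mb of Il10. Cd14, a receptor for bacterial lipopolysaccharide, rose 5.71-fold, the neutrophil granule gene Ngp 5.34-fold, Hamp, the iron hormone hepcidin, 4.69-fold, and Irak3, an inhibitor of Toll-like receptor signalling, 4.51-fold. Mmp8 (4.47-fold), Il1rn (4.32-fold), Ms4a8a (4.26-fold), Ifitm6 (3.70-fold) and Orm3 (3.63-fold) complete the 12 largest rises.

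The 12 largest falls were led by Car3, Atp6v0d2 and Aqp8. Car3, a carbonic anhydrase, dropped from 12.74 ± 0.34 to 9.21 ± 1.08 (SD, n = 4 each; 11.6-fold; limma adjusted p = 0.00614). Atp6v0d2, a proton pump subunit, was 8.20-fold lower, the water channel Aqp8 5.36-fold, Scd1, which desaturates fatty acids, 5.01-fold, and the peptidase Mme 4.14-fold. Serpina6, the carrier of corticosteroids in blood, was 3.85-fold lower, as was Abca8a. Mup-ps12, Tlcd2, the transporter Slc22a7, Cyp3a44 and Osgin1 were 3.53-, 3.52-, 3.50-, 3.50- and 3.33-fold lower. The lower group mean was near or below the array medians of 6.09 to 6.22 for Ctse (6.26), Chil1 (6.06), Ngp, Ifitm6 (6.29), Mme (5.81), Mup-ps12 (3.90) and Cyp3a44 (4.34). No detection call comes with the values, so these folds and their ranks are uncertain.

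In all, 699 of 22180 genes were called, 347 higher and 352 lower in the arrays labelled knockout, and 114 of them differed at least 2-fold (58 higher, 56 lower). The groups did not overlap in 694 of the 699, which a call with 4 against 4 arrays makes likely and which adds no separate support. Among all genes 12.9% had groups apart, against 2.86% that chance gives for 4 against 4. With each array shifted to a common median the split was 236 higher and 393 lower. The count depended on single arrays: it was 207, 237, 238 and 410 without wild-type replicates 1, 2, 3 and 4, and 207 without knockout-labelled replicate 4, while 611 genes were lower without knockout-labelled replicate 1. Of the 77 named genes that were called, 37 kept the call in each of the 8 fits without 1 array. Hamp lost it without any array but wild-type replicate 4 (adjusted p up to 0.120), and Cyp3a44 without wild-type replicate 2 (0.0521). Serpina6 lost it without wild-type replicates 1, 2 or 3 (up to 0.0657), Mup-ps12 without wild-type replicates 1 or 3 or knockout-labelled replicate 4 (up to 0.0777), Tlcd2 without wild-type replicates 1, 2 or 3 or knockout-labelled replicates 2 or 4 (up to 0.0812), and Orm3 without wild-type replicates 1 or 3 or knockout-labelled replicates 2, 3 or 4 (up to 0.0878).

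**Figure D1:**
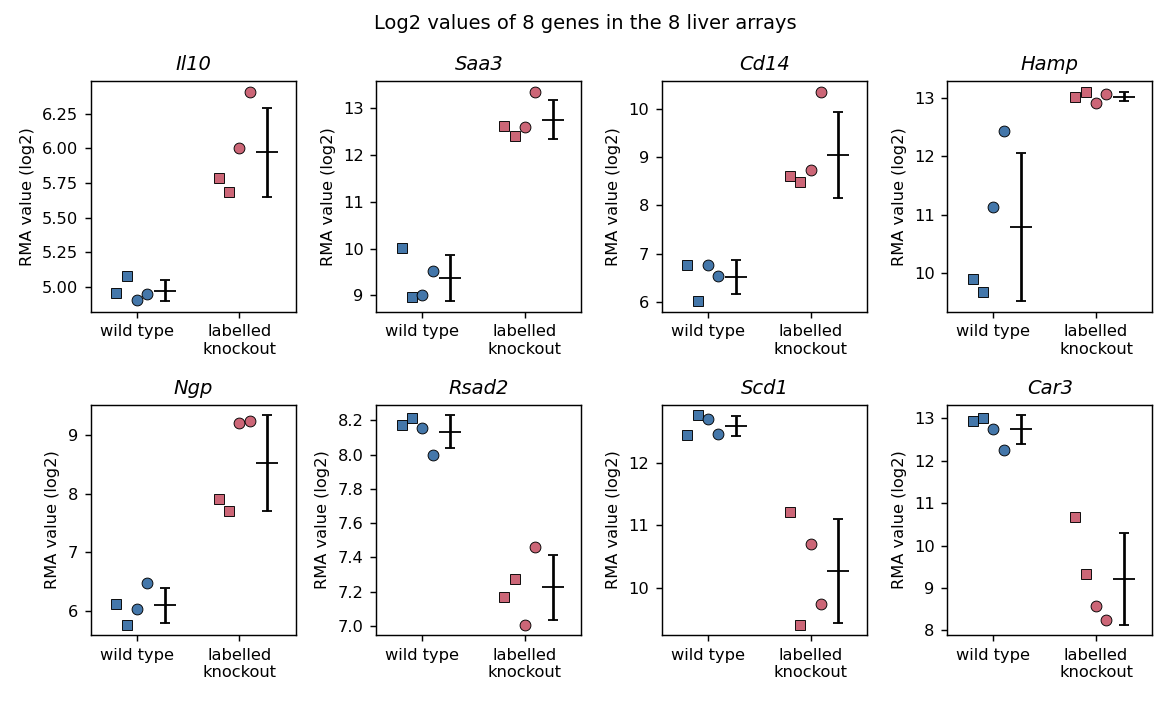
Log2 RMA values (vertical axes, each with its own range) of 8 named genes in the 4 wild-type arrays (blue) and the 4 labelled knockout (red), with squares for arrays with Y-linked signal, circles for arrays with Xist signal, and bars for mean ± SD. In each of the 8 genes the 4 values of a group lie apart from the 4 of the other, as for Saa3 (9.37 ± 0.50 against 12.75 ± 0.42) and Car3 (12.74 ± 0.34 against 9.21 ± 1.08). The rule that picked Saa3, Cd14, Hamp, Ngp, Scd1 and Car3 required groups that do not overlap.

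Acute-phase genes, which the liver makes in inflammation, were higher as a list in the arrays labelled knockout. Neutrophil and macrophage markers were higher in the same arrays (list medians 0.80 and 0.53), and RNA of whole liver does not tell which cells made these transcripts. Of 27 measured, 7 rose and 20 did not pass, and 16 passed adjusted over the list alone, all higher. Saa3, Orm3, Cd14 and Il1rn rose as given above, Lcn2, which binds bacterial iron carriers, rose by 0.82 (log2), and Lbp, which hands lipopolysaccharide to Cd14, by 0.61. Saa2 was already at 12.65 ± 0.43 in wild-type arrays and 13.27 ± 0.07 in the others (log2 difference 0.62; adjusted p = 0.0867). The list passed camera (adjusted p = 2.11e-10), and had adjusted p = 0.296 with an estimated correlation. Lcn2 lost its call without wild-type replicates 1 or 3 or knockout-labelled replicates 3 or 4 (adjusted p up to 0.0790).

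Genes of IL-10 and STAT3 signalling and of cytokines and NF-kB were higher as lists, in the same arrays as neutrophil and macrophage markers (list medians 0.80 and 0.53). Of 16 IL-10 and STAT3 genes, which include receptor subunits and Il10 itself, 4 rose and 12 did not pass, with 10 higher adjusted over the list alone. The 4 called over all genes were Il1rn (2.11), an antagonist of interleukin-1, the hemoglobin scavenger receptor Cd163 (1.01), also among the macrophage markers, Il10 itself and Il4ra (0.39). Of 26 cytokines and NF-kB targets, 6 rose and 20 did not pass, with 10 higher adjusted over the list alone. Among them were the adhesion molecule Icam1 (0.91), the neutrophil attractant Cxcl2 (0.68), the NF-kB inhibitor Nfkbia (0.62) and the granulocyte growth factor Csf3 (0.39). Both lists passed camera (adjusted p = 2.26e-06 and 0.000184), each with adjusted p = 0.218 with an estimated correlation. Csf3 lost its call without any array but knockout-labelled replicate 4 (adjusted p up to 0.101), and Il4ra without any wild-type array or knockout-labelled replicate 4 (up to 0.0859). Nfkbia lost it without wild-type replicates 2, 3 or 4 or knockout-labelled replicate 4 (up to 0.0790), and Cxcl2 without wild-type replicates 1, 3 or 4 or knockout-labelled replicates 3 or 4 (up to 0.0942).

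Neutrophil, macrophage and monocyte markers were higher as lists. Of 19 neutrophil genes, 11 rose, 1 fell and 7 did not pass, with 14 higher and 1 lower adjusted over the list alone; Ngp (2.42), Mmp8 (2.16) and the chemokine receptor Cxcr2 (0.86) rose, while Prtn3, a granule protease made early in neutrophil maturation, fell by 0.72. Of 18 Kupffer cell and macrophage genes, 7 rose and 11 did not pass, with 15 higher adjusted over the list alone; these include Cd163 (1.01), the complement subunits C1qb (0.64) and C1qc (0.51) and the growth factor receptor Csf1r (0.56). Of 16 monocyte and dendritic cell genes, 6 rose and 10 did not pass, with 6 higher adjusted over the list alone; the Fc receptor Fcgr4 (1.37), Plac8 (1.06), Chil3 (1.05) and Flt3 (0.44) were among them. Of 21 T and NK cell genes, Il2rb (0.67) and Ccl5 (0.52) rose and 19 did not pass, with 2 higher adjusted over the list alone; Cd28 (0.77) passed with the block for Xist and Y-linked signal (adjusted p = 0.0413). The 4 lists passed camera (adjusted p = 2.30e-10 for neutrophils and for macrophages, 0.000114 for monocytes, 0.00313 for T and NK cells), and had adjusted p = 0.218, 0.259, 0.218 and 0.431 with an estimated correlation. Chil3 lost its call without wild-type replicate 3 (adjusted p = 0.0502), Plac8 without wild-type replicates 1 or 2 (up to 0.0615) and Csf1r without these or knockout-labelled replicate 4 (up to 0.0721). C1qc, Il2rb and Ccl5 lost theirs without wild-type replicates 1, 2 or 4 or knockout-labelled replicates 2 or 4 (up to 0.0812, 0.104 and 0.109), and the T and NK list had adjusted p = 0.108 in the 4 arrays with Xist signal. Against the wild-type mean of each gene, the T and NK median was 0.11, 0.11, 0.19 and 0.18 in knockout-labelled replicates 1 to 4. In wild-type replicates 1 to 4 it was -0.16, 0.03, 0.09 and 0.13, so the groups overlapped. Without wild-type replicate 1 that list had camera adjusted p = 0.0322.

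Among markers of red cells and of the other liver cell types, few single genes were called. Of 18 erythroid genes, Car1 (-0.95) and Tspan33 (-0.52) fell and 16 did not pass (camera adjusted p = 0.0666, but 0.00281 without wild-type replicate 3 and 0.00994 without knockout-labelled replicate 3; 3 lower adjusted over the list alone). That list also passed as lower with low genes left out (0.0482), quantile normalization (0.00497), cyclic loess (0.00592), array weights (0.0189) and in the arrays with Y-linked signal (2.67e-05; median -0.13, against 0.04 in those with Xist signal). The mean of 6 rows that name adult hemoglobin genes or Alas2 with other genes differed by -0.64 (SE 0.21; exact two-sided permutation p = 0.0286, the smallest possible), opposite to the neutrophil markers. Of 19 stellate cell and matrix genes, Lrat (-1.01), which stores vitamin A, and the proteoglycan Lum (-0.94) fell, Vim (0.53) rose and 16 did not pass, with 2 higher and 5 lower adjusted over the list alone; the list passed camera as lower (adjusted p = 0.0234, and adjusted p = 0.631 with an estimated correlation), but not without knockout-labelled replicate 2 (0.272) or wild-type replicate 3 (0.0970), with low genes left out (0.0628), quantile normalization (0.0517), cyclic loess (0.0542) or in the arrays with Xist signal (0.0984). Of 15 sinusoidal endothelial genes Lyve1 rose by 1.05 and 14 did not pass (camera adjusted p = 0.899), with 1 higher and 1 lower adjusted over the list alone; Emcn had -0.45 (adjusted p = 0.0792). Of 13 bile duct genes Pkhd1 fell by 0.84 and 12 did not pass (camera adjusted p = 0.116, but 0.0479 without wild-type replicate 4), with 1 higher and 2 lower adjusted over the list alone. No gene was called by limma among 14 B and plasma cell, 12 platelet, 15 pancreatic and 13 adipocyte and muscle markers (1, 2, 2 and 1 at an unadjusted p under 0.05; camera adjusted p = 0.651, 0.0660, 0.574 and 0.399), where the counts adjusted over the list alone were 0, 2 higher, 0 and 0. With the block for Xist and Y-linked signal the platelet integrin Itgb3 (0.72; adjusted p = 0.0389) and the bile duct gene Sox9 (0.52; adjusted p = 0.0396) passed. The platelet list passed without wild-type replicate 1 (0.00235) or knockout-labelled replicate 1 (0.0239), with a common median (0.0494) and in the arrays with Xist signal (0.0237). Lrat and Lum lost their calls without any array but knockout-labelled replicate 1 (adjusted p up to 0.124 and 0.135), and Vim and Pkhd1 without wild-type replicate 1 or knockout-labelled replicate 4 (up to 0.0549 and 0.0793). Car1 lost it without wild-type replicates 2 or 3 or knockout-labelled replicate 4 (up to 0.0669), and Tspan33 without wild-type replicates 1, 2 or 3 or knockout-labelled replicates 3 or 4 (up to 0.127).

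Hepcidin rose, while the list of its signalling genes did not pass in all 8 arrays as deposited. Hamp read 10.79 ± 1.26 in wild-type arrays and 13.02 ± 0.08 in the others (SD, n = 4 each; limma adjusted p = 0.0425); the wild-type values were 9.91, 9.69, 11.1 and 12.4. Its difference was 3.26 in the arrays with Y-linked signal and 1.20 in those with Xist signal (limma interaction adjusted p = 0.521), and its call was lost without any array but wild-type replicate 4 (adjusted p up to 0.120). Of 21 hepcidin and BMP-SMAD genes it alone was called, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.204). The list passed as higher with quantile normalization (0.0160), with cyclic loess (0.0200) and in the arrays with Y-linked signal (0.000128), where its median was 0.08 against -0.03 in those with Xist signal. With the block for Xist and Y-linked signal Hfe (0.36; adjusted p = 0.0431) and Tmprss6 (-0.48; adjusted p = 0.0425) passed too. Values of Smad7 (0.39; adjusted p = 0.0981), Id1 (0.17), Bmp6 (0.01) and the second hepcidin gene Hamp2 (0.05) did not pass. Of 26 iron and heme genes, Lcn2, Hmox1 (0.62), which degrades heme, and the zinc and iron importer Slc39a14 (0.58) rose, Steap3 (-0.59), within 20 Mb of Il10, fell, and 22 did not pass; 8 were higher and 5 lower adjusted over the list alone. That list did not pass (camera adjusted p = 0.952), and its median of -0.02 differs in sign from its mean of 0.03 and from camera's direction. The transferrin receptor Tfrc had -0.02 (adjusted p = 0.972). Slc39a14 and Steap3 lost their calls without wild-type replicates 1, 2 or 3 or knockout-labelled replicate 4 (adjusted p up to 0.0950 and 0.0924), as did Slc39a14 without knockout-labelled replicate 3, and Lcn2 without wild-type replicates 1 or 3 or knockout-labelled replicates 3 or 4 (up to 0.0790).

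Type I interferon genes were lower as a list. Of 23 type I interferon genes, Rsad2, an antiviral enzyme, fell by 0.91 and Mx2 by 0.56, and 21 did not pass, with 6 lower adjusted over the list alone; Cmpk2 (-0.99) passed with the block for Xist and Y-linked signal (adjusted p = 0.0405). The list passed camera (adjusted p = 3.20e-05; adjusted p = 0.509 with an estimated correlation), but its median was -0.62 in the 4 arrays with Xist signal and 0.08 in the 4 with Y-linked signal, where camera gave adjusted p = 0.289; the difference between the sets was not tested for the list. Against the wild-type mean of each gene, its median was lowest in knockout-labelled replicate 3, at -0.84. It was between -0.19 and 0.04 in the other arrays of that group. Without knockout-labelled replicate 3 the list had camera adjusted p = 0.0131. Of 29 interferon-gamma and antigen presentation genes Cxcl11 fell by 0.42 and 28 did not pass (camera adjusted p = 0.104, but 0.0119 without wild-type replicate 3 and 1.25e-05 without knockout-labelled replicate 3; 2 higher and 1 lower adjusted over the list alone), where Socs1 (0.72) passed with that block (adjusted p = 0.0461). Cxcl11 went against the direction of this list, which passed as higher in the arrays with Y-linked signal (1.72e-08; median 0.35, against -0.05 in those with Xist signal), and with quantile normalization (0.0233), cyclic loess (0.0200) and array weights (0.00263). Of 28 complement and coagulation genes, the lectin Mbl2 fell by 1.14 and C8g by 0.61, and 26 did not pass, with 1 higher and 2 lower adjusted over the list alone; its camera adjusted p of 0.0349 became 0.559 with an estimated correlation, and 0.0821, 0.128 and 0.0620 without wild-type replicate 1, knockout-labelled replicate 3 or replicate 4. It also missed 0.05 with low genes left out (0.131), quantile normalization (0.179), cyclic loess (0.328), array weights (0.0609), the replicate block (0.0528), members near Il10 left out (0.0630) and in the arrays with Y-linked signal (0.278). Mx2, Cxcl11 and C8g lost their calls without any array but knockout-labelled replicate 1 (adjusted p up to 0.110, 0.0943 and 0.132).

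Genes of fatty acid and triglyceride synthesis were lower as a list. Of 20 fatty acid and triglyceride synthesis genes, 8 fell and 12 did not pass, with 16 lower adjusted over the list alone; Scd1 (-2.32), Thrsp (-1.06), Pklr (-0.94) and Mlxipl (-0.80), the carbohydrate-sensing activator of such genes, were among them. The list had the lowest camera p of the 31 (adjusted p = 4.54e-11), and adjusted p = 0.218 with an estimated correlation. None of 18 cholesterol synthesis genes was called by limma over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05), but all 18 had negative log2 differences (median -0.59; camera adjusted p = 9.30e-05; adjusted p = 0.559 with an estimated correlation). Against the wild-type mean of each gene, the median of that list was -2.04 in knockout-labelled replicate 3. It was 0.24 in replicate 1, -0.63 in replicate 2 and -0.07 in replicate 4. Dhcr7 read 8.81 in replicate 3 against 9.88 to 10.8 in the other arrays of the group. Without replicate 3 the list had adjusted p = 0.0212, and in the arrays with Y-linked signal 0.0581. Pklr lost its call without any wild-type array or knockout-labelled replicate 4 (adjusted p up to 0.0774).

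**Figure D2:**
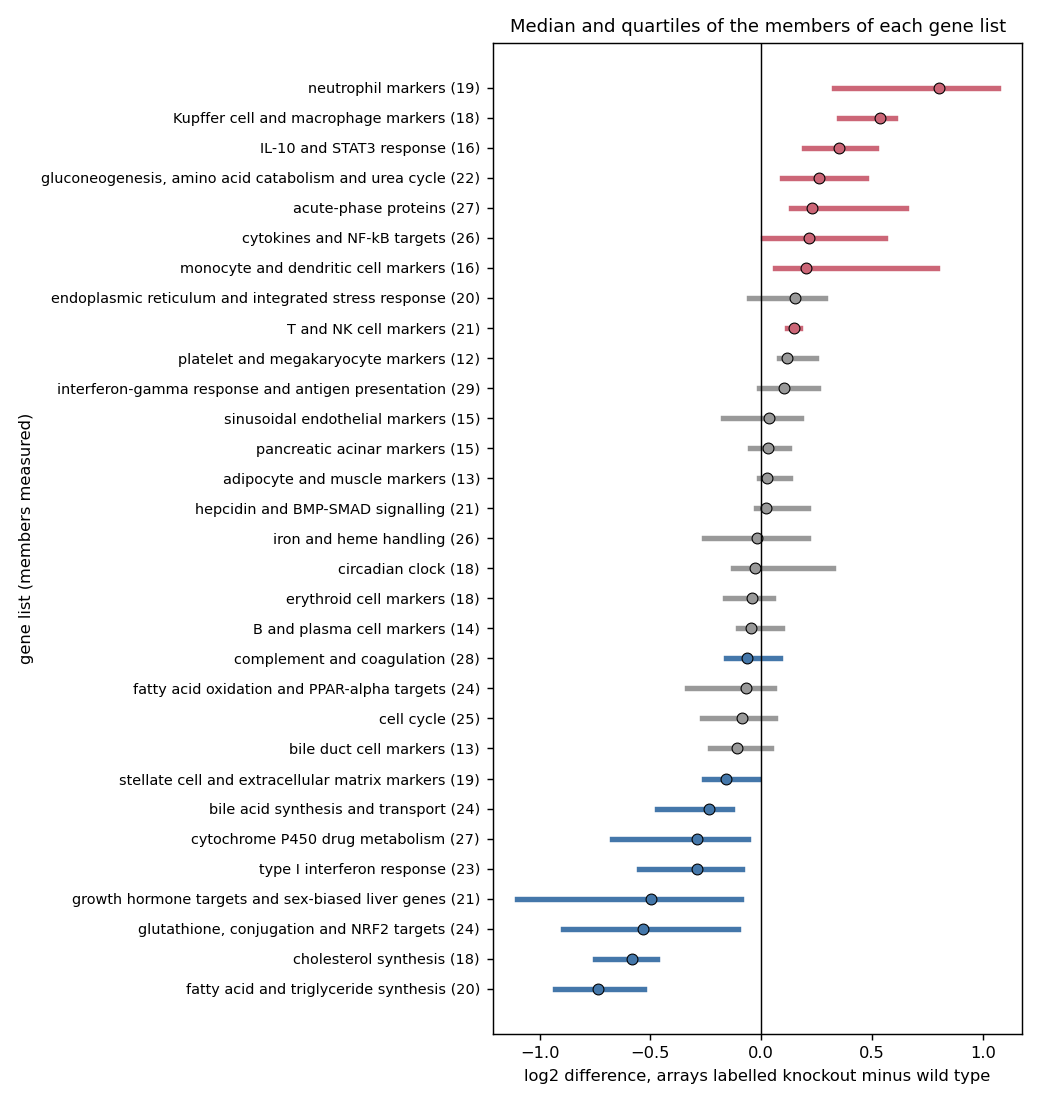
Median (point) and quartiles (line) of the log2 differences of the measured members of each of the 31 lists, arrays labelled knockout minus wild type, with red for lists that passed camera as higher, blue as lower and grey not. The medians run from -0.74 for fatty acid and triglyceride synthesis to 0.80 for neutrophil markers.

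Drug metabolism and conjugation genes were lower as lists. Of 27 cytochrome P450 genes and regulators, 5 fell and 22 did not pass, with 6 lower adjusted over the list alone; Cyp3a44 (-1.81), Cyp3a59 (-1.66), Cyp3a11 (-1.25) and Cyp2c29 (-0.73) were among them. Of 24 glutathione, conjugation and NRF2 target genes, 6 fell and 18 did not pass, with 10 lower adjusted over the list alone; they include the glutathione transferases Gsta4 (-1.38), Gstt1 (-1.20) and Gstm4 (-0.97). Both lists passed camera (adjusted p = 1.25e-05 and 4.64e-07), with adjusted p = 0.259 and 0.301 with an estimated correlation. List medians against the wild-type mean of each gene overlapped between the groups. For P450 genes they were -0.45, -0.23, -0.08 and -0.74 in knockout-labelled replicates 1 to 4, against -0.14 in wild-type replicate 2. For glutathione genes they were -0.25, -0.30, -0.68 and -0.77, against -0.33 in wild-type replicate 4. Gsta4 and Gstm4 lost their calls without wild-type replicates 1, 2 or 3 or knockout-labelled replicate 4 (adjusted p up to 0.0806 and 0.0625), as did Gsta4 without knockout-labelled replicate 2 and Cyp3a44 without wild-type replicate 2 (0.0521).

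Bile acid genes and growth hormone targets were lower as lists with few single calls. Of 24 bile acid genes, the canalicular exporter Abcb11 fell by 0.70 and 23 did not pass, with 3 lower adjusted over the list alone. The bile acid list had camera adjusted p = 0.000121, and 0.346 with an estimated correlation. Against the wild-type mean of each gene, its median was -0.12, -0.11, -0.14 and -0.42 in knockout-labelled replicates 1 to 4. In wild-type replicates 1 to 4 it was 0.13, -0.10, 0.05 and -0.12, so mainly knockout-labelled replicate 4 stood apart. Without that replicate the list had camera adjusted p = 0.00284. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 difference of -1.94 (limma adjusted p = 0.286). It read 10.4 and 11.3 in knockout-labelled replicates 1 and 2, which carried Y-linked signal. In knockout-labelled replicates 3 and 4, which carried Xist signal, it read 7.75 and 5.95. Of 21 growth hormone and sex-biased genes, Cyp3a44 fell and 20 did not pass, with 3 lower adjusted over the list alone (camera adjusted p = 0.000998; adjusted p = 0.218 with an estimated correlation and 0.0628 with the lowest 40% of genes left out). The transporter Slco1a1 had -2.80 (adjusted p = 0.0767) and passed with a block for Xist and Y-linked signal (adjusted p = 0.00958; 0.00958 to 0.226 over 20 alternatives), as did Igfals (-0.95; 0.0419) and the growth hormone receptor Ghr (-0.50; 0.0282). Cyp3a44 lost its call without wild-type replicate 2 (0.0521). Abcb11 lost its call without any array but knockout-labelled replicate 1 (adjusted p up to 0.0979).

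Among the remaining metabolic lists, gluconeogenesis, amino acid and urea cycle genes were higher as a list. Of 22, Tat (0.51), which degrades tyrosine, and the ornithine carrier Slc25a15 (0.36) rose and 20 did not pass, with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00138; adjusted p = 0.431 with an estimated correlation and 0.0611 in the arrays with Y-linked signal). Of 24 fatty acid oxidation genes, Acaa1b (-1.04) and Ppara (-0.81) fell and 22 did not pass (camera adjusted p = 0.0704, but 0.0322, 0.0378, 0.0322 and 0.0116 without wild-type replicates 1 or 2 or knockout-labelled replicates 1 or 4; 2 lower adjusted over the list alone). Of 25 cell cycle genes, Ccnd1 (-1.42) and Mcm6 (-0.74), within 20 Mb of Il10, fell and 23 did not pass (camera adjusted p = 0.0531, but 0.00336, 0.00318 and 0.0237 without wild-type replicates 1 or 4 or knockout-labelled replicate 1; 3 lower adjusted over the list alone). Of 18 clock genes, Per1 rose by 0.87 and 17 did not pass (camera adjusted p = 0.895; 2 higher adjusted over the list alone), and the list's median of -0.03 differs in sign from its mean of 0.12 and from camera's direction. None of 20 endoplasmic reticulum stress genes was called by limma over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05; camera adjusted p = 0.0943, but 0.0428 and 0.00748 without knockout-labelled replicates 2 or 3). The last list also passed as higher with a common median (0.0491), quantile normalization (0.0245), cyclic loess (0.0232), array weights (0.0268), the replicate block (0.0394) and in the arrays with Xist signal (0.0243). Cell cycle genes passed as lower with low genes left out (0.0250), quantile normalization (0.0104), cyclic loess (0.0120) and in the arrays with Xist signal (0.0237), and fatty acid oxidation genes in the latter (0.00324; median -0.27, against 0.07 in those with Y-linked signal). With the block for Xist and Y-linked signal Xbp1 (0.35, adjusted p = 0.0394) of the endoplasmic reticulum stress list passed, as did Pcx (0.27, adjusted p = 0.0456) among gluconeogenesis genes. Slc25a15 lost its call without any 1 array (adjusted p up to 0.119), Ppara and Ccnd1 without any but knockout-labelled replicate 1 (up to 0.117 and 0.0946), and Per1 without any but knockout-labelled replicates 1 and 3 (up to 0.101). Tat lost it without wild-type replicates 2, 3 or 4, Acaa1b without wild-type replicates 1, 2 or 3 and Mcm6 without wild-type replicates 2 or 3 or knockout-labelled replicate 2, and each of them without knockout-labelled replicate 4 (up to 0.0758, 0.0660 and 0.0787).

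Across the 31 lists, 8 passed camera as higher and 9 as lower, and none of the 17 passed with an estimated correlation (adjusted p between 0.218 and 0.631). Of these, 8 passed fry: acute-phase, IL-10 and STAT3, cytokines and NF-kB, fatty acid synthesis, growth hormone, macrophage, neutrophil and monocyte genes.

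Although all 8 mice are labelled female, 4 arrays carried Y-linked transcripts and little Xist, the RNA that silences an X chromosome in females. Wild-type and knockout-labelled replicates 1 and 2 had means of 3 Y-linked genes (Eif2s3y, Kdm5d and Uty) between 8.20 and 8.52 and Xist between 5.62 and 6.32. Replicates 3 and 4 of both groups had Y-linked means between 4.30 and 4.48 and Xist between 11.7 and 11.8. The sets hold 2 arrays of each group, so they are balanced over the comparison. With the sets as a block 1038 genes were called, 691 of them among the 699. Of the named genes 12 were called with this block only, each given with its group above, and 0 without it only. Within the sets, from a model that shares the spread of all 8 arrays, 756 genes were called in the 4 arrays with Xist signal (265 higher, 491 lower) and 61 in the 4 with Y-linked signal (36 higher, 25 lower), and these settings were chosen after seeing the data. A test of the difference between the sets passed for 6 genes, none of them among the 699, by limma, with 1215 genes at an unadjusted p under 0.05.

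**Figure D3:**
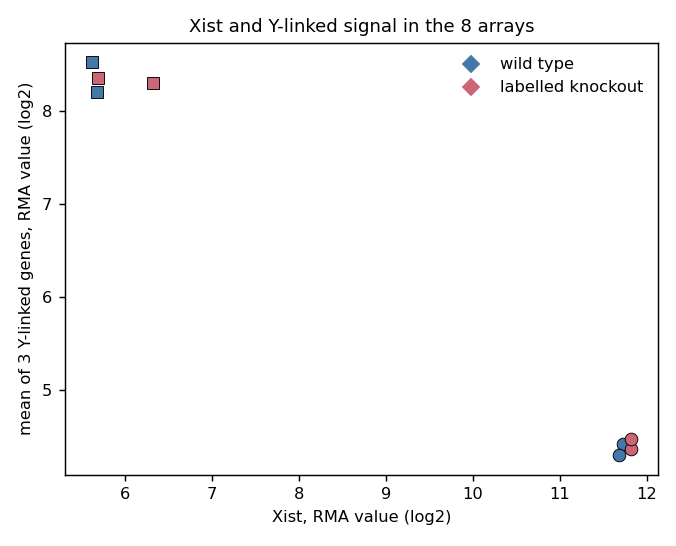
Xist (horizontal axis) against the mean of 3 Y-linked genes (vertical axis), log2 RMA values, in the 4 wild-type arrays (blue) and the 4 labelled knockout (red), squares and circles marking the sets. The 4 squares have Xist between 5.62 and 6.32 and the 4 circles between 11.7 and 11.8, with 2 arrays of each group in each set.

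The arrays differed in spread. The interquartile range of deviations from the gene medians was 0.276 in knockout-labelled replicate 3 and between 0.125 and 0.204 in the others, and the group means were 0.167 and 0.179 (exact two-sided permutation p = 0.857). The first principal component held 45.2% of the variance and separated the groups (exact two-sided permutation p = 0.0286, the smallest possible). Without that replicate 577 genes were called.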

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

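Tests of male RNA in female samples, of hepatocyte share, of residual blood and of gene clusters elsewhere in the genome were chosen after the result was seen. Those of the 35 splits and of genes near Il10 were not. The test of male mice was written before its own result, but its 4 arrays were set apart by Y-linked signal seen in the data. The restriction to 18 splits also rests on that signal.

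Single arrays stood far from the other 3 of their group in 12 of 288 sets of 4 values, where chance gives 14.4. In the arrays labelled knockout these were Ctse at 9.90 and Lrat at 8.82 in replicate 1, both above the others, Clec1b at 9.07 in replicate 1, below them, and Cd14 at 10.4 (above) and Serpind1 at 12.2 (below) in replicate 4. In the wild-type arrays they were Tfrc at 8.66 and Mx2 at 7.81 in replicate 1, Pou2af1 at 6.67 in replicate 2 and Cxcr2 at 7.46 in replicate 3, all above, and Stab1 at 9.12 and Cldn7 at 4.94 in replicate 2 and Cela3b at 3.95 in replicate 3, all below. The number does not exceed chance, and no explanation is offered.

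Rows that name no gene or several genes were left out of the comparison of genes. Among 17824 such rows 27 passed an adjusted p of 0.05 in limma, 8 higher and 19 lower in the arrays labelled knockout, and the 7 of them that name several genes were all lower. Each of the 7 names either 4933409K07Rik and Gm3893, at times with further genes, or Entpd4 and Entpd4b. Rows 17424360 and 17434197 had the same log2 difference (-1.15) and SE. The 7 rows are therefore not independent observations.

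The 699 called genes could be a product of how 8 arrays fall into groups. Of 35 splits into 4 and 4, the real one called 699 genes and the highest other 13. So 1 split of 35 gave as many, the smallest share that 35 splits allow. This argues against chance but cannot exclude it. Splits that mix the groups also hold the group difference in their spread, which lowers their counts. The split with 13 is the one by Xist and Y-linked signal. The real split parts that signal evenly, and among the 18 that do, the highest other called 0 genes by limma, but 18 are too few for a share under 0.05.

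Y-linked signal appeared in 4 arrays labelled female, with a lowest mean of 8.20 among them. Male RNA mixed into female samples would keep Xist high, but the highest Xist value of the 4 lies 5.36 log2 units below the lowest of the others, which argues against a mixture. That the 4 arrays come from male mice fits a test on fixed sex-biased liver genes: all 9 male-biased genes were higher in them and all 6 female-biased genes lower, with medians 4.49 apart (exact two-sided permutation p over genes = 0.00300). That p treats the genes as independent and leaves out the spread between arrays. The smallest differences were 0.15 for C8b and -0.24 for Hao2, and within the arrays labelled knockout Hao2 went the other way (0.61). Whether the sex entry of the labels or the sample itself was exchanged stays open, and the sets are balanced over genotype.

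Called genes were denser near Il10 on its chromosome. Within 20 Mb, 13 of 197 genes were called against 681 of 21793 elsewhere (odds ratio 2.19, 95% interval 1.14 to 3.86; Fisher's exact p = 0.0117), Ctse and Chil1 among them, while the ratio was 1.92 within 10 Mb (Fisher's exact p = 0.0627) and 1.76 within 5 Mb (Fisher's exact p = 0.167). Clusters as dense were rare elsewhere, in 0.406% of 21196 overlapping windows of the same size, which argues against clustering that is common in the genome. Donor-strain sequence kept around the mutated locus may account for the excess, as may a response of genes that happen to lie there, and no sequence was used here to part them. Of the 13, 9 were higher and 4 lower.

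Macrophage and neutrophil markers were higher in the arrays labelled knockout. A lower share of hepatocytes would raise every other cell type alike, but endothelial, stellate and bile duct markers had a median of -0.11 against 0.56 for the myeloid markers (difference -0.670, SE 0.0767). That SE resamples marker genes as if independent and leaves out the spread between arrays, so it overstates the precision. In single knockout-labelled arrays, list medians against wild-type means ran from 0.24 to 0.96 for the myeloid lists. They ran from -0.39 to 0.13 for the endothelial, stellate and bile duct lists. These values argue against a lower share of hepatocytes as the whole cause. More blood left in the tissue would raise hemoglobin rows, but these differed by -0.635 (SE 0.210 over arrays). This argues against more blood unless red cells themselves were fewer, a possibility these arrays do not settle. More myeloid cells in the liver, or more of these transcripts per cell, may each account for the rise and stay open as untested hypotheses.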

How the results depend on the processing

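The block for Xist and Y-linked signal, the arrays of each such set alone and the lists without members near Il10 were tests chosen after the result was seen. No call of a gene or list reversed in any alternative; 19 of 2826 compared values of 5 named genes changed sign, all past the threshold in neither setting. Of the named genes' values in alternatives 2335 stayed on their side of the threshold, 89 gained and 383 lost a call, and of the lists' 594, 41 and 47. The cause of the changes below was not tested. Counts of genes stayed within 1.5 times of 699 under the filter, the mean of rows, all 3 rescalings, trend and robust settings, and array weights. With every row of the table tested, 332 passed (170 higher, 162 lower). An adjusted p below 0.1 gave 1685 (844 higher, 841 lower) and a 1.5-fold minimum 377 (179 higher, 198 lower). An unmoderated test called 0 genes (0 higher, 0 lower), with 4141 at an unadjusted p under 0.05, against 699 and 4700 by limma, and left Il10 at 1.00 with an adjusted p of 0.0975. The block for Xist and Y-linked signal gave 565 lower genes, and the 4 arrays with Y-linked signal alone 61 (36 higher, 25 lower), with Il10 at 0.72.

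Leaving out 1 array gave 207 to 1040 genes, 109 to 429 higher and 96 to 611 lower. Adjusted p values of complement and coagulation then ran from 0.00579 to 0.128 and those of stellate markers from 0.000892 to 0.272. The 4 lowest counts were without wild-type replicates 1, 2 and 3 and knockout-labelled replicate 4.

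Replicate numbers did not match single arrays: deviations of same-numbered arrays correlated at 0.27, 0.04, -0.10 and 0.29. Only 0 of 4 wild-type and 2 of 4 knockout-labelled arrays correlated best with their own number. Each wild-type array correlated best with a knockout-labelled array of its own Xist or Y-linked set. Since same-numbered arrays share that set, a replicate block also takes up the difference between the sets. The replicate block gave 497 genes with 225 higher, 387 of them shared with the unpaired comparison, and an adjusted p of 0.0528 for complement and coagulation.

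With an estimated correlation 0 of the 17 lists passed. The adjusted p values were 0.218 for IL-10 and STAT3, cytokines and NF-kB, fatty acid synthesis, growth hormone, neutrophil and monocyte lists, 0.259 for P450 and macrophages, 0.296 for acute-phase, 0.301 for glutathione, 0.346 for bile acids, 0.431 for gluconeogenesis and for T and NK cells, 0.509 for type I interferon, 0.559 for complement and for cholesterol, and 0.631 for stellate markers. With fry 8 passed, and P450 (0.0566), glutathione (0.0791), gluconeogenesis and T and NK cells (0.0834 each), bile acids (0.159), type I interferon (0.243), complement (0.293), cholesterol (0.351) and stellate markers (0.488) did not.

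Complement and coagulation also lost its call under the filter (0.131), quantile normalization (0.179), cyclic loess (0.328), array weights (0.0609), the arrays with Y-linked signal (0.278) and without members near Il10 (0.0630). Stellate markers lost theirs under the filter (0.0628), quantile normalization (0.0517), cyclic loess (0.0542) and in the arrays with Xist signal (0.0984). Growth hormone genes had 0.0628 under the filter, T and NK cells 0.108 in the arrays with Xist signal, and type I interferon 0.289, cholesterol 0.0581 and gluconeogenesis 0.0611 in those with Y-linked signal. The density of called genes near Il10 had an odds ratio of 1.92 within 10 Mb and 1.76 within 5 Mb. Without the lowest 40% of genes by mean, the spread of the arrays differed between groups by 0.0324 (exact two-sided permutation p = 0.6). No detection call comes with these values. The 3 Y-linked genes read 4.08 to 4.61 in the arrays with Xist signal and Xist 5.62 to 6.32 in the others, so rows without their transcript read different levels, no common floor can be set from them, and folds of low rows are uncertain.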

Other observations

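The tests of symbol roots, of both measures of sex bias and of the difference between the sets were all chosen after the result was seen. Gene groups were also sought by the root of their symbols, and their members were named after their values were seen. Genes of the fixed lists were not left out of these groups. Among 325 roots with at least 8 tested genes, 2 held more higher and 4 more lower calls than the other genes (one-sided Fisher's exact tests, adjusted over both directions). Genes of colony-stimulating factors and their receptors rose, 5 of 8 (adjusted p = 1.59e-05): Csf2rb2 by 1.07 (log2), Csf1r by 0.56, Csf2rb by 0.54, Csf3r by 0.43 and Csf3 by 0.39. Of 12 Toll-like receptor genes 5 rose (adjusted p = 0.000143), Tlr13 by 0.84, Tlr8 by 0.69, Tlr9 by 0.43, Tlr4 by 0.42 and Tlr11 by 0.39. Csf1r and Csf3r are themselves among the macrophage and neutrophil markers, lists that had medians of 0.53 and 0.80, so these groups are not separate from the rise of those markers. Csf3 is also in the fixed list of cytokines and NF-kB targets.

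The carboxylesterases, which hydrolyse lipid esters and drugs, held the densest falls, 7 of 19 (adjusted p = 6.64e-06), with Ces2e at -1.62, Ces1d at -1.41, Ces2a at -1.29 and Ces1e at -1.20. Carbonic anhydrases followed with 4 of 14 (adjusted p = 0.00894), Car3 at -3.53, Car2 at -1.57, Car1 at -0.95 and Car5b at -0.94, where Car1 is itself an erythroid marker and the hemoglobin rows differed by -0.64, then Abca transporters with 4 of 16 lower (adjusted p = 0.0127) and Cyp genes with 8 of 98 (adjusted p = 0.0183). In these last groups Abca1 (0.65) and Cyp4f18 (0.40) were called the other way. Of the lower Cyp genes, Cyp2c29, Cyp3a59, Cyp3a44, Cyp3a11 and Cyp2f2 are members of the fixed cytochrome P450 list. The Cyp group is therefore not separate from that list. The 33 members called in the direction of their group all kept their sign after a shift to a common median, quantile normalization and cyclic loess, and 28, 31 and 31 stayed called. Members of such groups are not independent, and probes of close relatives can read each other's transcripts.

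A hypothesis from the same data is that the sex bias of liver genes was smaller in the arrays labelled knockout. Genes were picked by a 4-fold difference between 1 wild-type array of each set and then read in the other wild-type pair. A first measure, the median ratio of single genes with a floor of 0.5 on the wild-type difference, gave 0.512 (18 genes; 95% bootstrap interval 0.253 to 0.631), and 0.674, 0.591 and 0.633 for the other ways of picking. Since such a floor favours ratios below 1, it was replaced, after that result was known, by the ratio of mean differences without a floor. This gave 0.503 (0.379 to 0.621) for the same picking arrays and 0.646, 0.551 and 0.807 for the other ways, the last with an interval of 0.552 to 1.34 that includes no change. The bootstrap of both measures resampled genes as if independent and leaves out the spread between arrays, so the intervals overstate the precision. The ways of picking also share the same arrays. A smaller sex bias therefore may or may not be present, and 2 arrays per set and genotype do not decide it.

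Of the 6 genes whose group difference itself differed between the sets by limma, Slc10a6 had log2 differences of 2.78 in the arrays with Xist signal and 0.62 in those with Y-linked signal (interaction adjusted p = 0.00661), Mir344d-2 of 2.59 and 0.39 (0.00214), and Rasd1 of 1.77 and 0.11 (0.0422). Cyp2d9, a male-biased gene, had 1.33 and -0.29 (0.0259), Slc22a29 -1.66 and 0.11 (0.0422), and Sytl5 -1.82 and -0.34 (0.0422). These genes were named after their values were seen.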
